A study of Mus musculus with 12 samples.

How the data were processed

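Liver RNA from 12 mice was measured by sequencing the 3' ends of polyadenylated transcripts. Per the labels' protocols, total RNA was extracted with Trizol, purified on RNeasy columns, turned into libraries with Lexogen's QuantSeq 3' kit and sequenced on an Illumina NextSeq instrument. Per the submitters' processing notes, the pipeline named cutadapt 1.9, HISAT2, featureCounts and limma, with the mm10 genome build. Versions of HISAT2, featureCounts and limma, the gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. The authors deposited 1 table of raw counts, whole numbers per gene and library with no normalization, for 51912 Ensembl gene identifiers. A symbol was found for 51633 of these identifiers and a position in the GENCODE M21 annotation of mm10 for 51719. Identifiers without a symbol held 0.0454% to 0.0550% of a library's counts and were kept. The 13 mitochondrially encoded genes are in the table with 0 counts in all libraries, so the list of these genes was not tested.

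Library totals ran from 19435391 to 32120426 counts. At such totals the counting error of an abundant gene is small beside the spread between animals. The 3 most abundant genes of a library held 6.80% to 10.2% of its counts together. Counts come from reads without molecular identifiers as far as the sources say, so counting errors cover sampling only. Every pair of libraries within a group differed beyond sampling noise, with a chi-square per degree of freedom of 19.4 to 137 over genes, and no library was treated as a copy of another. The labels number the animals separately, and the 12 libraries were taken as 12 animals.

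Groups were read from the genotype and diet labels. The samples, tests, gene lists, naming rule and alternatives were fixed before the data were examined, except those named in the closing section as chosen later. Tests used edgeR 4.0.16 in R 4.3.3. Genes with too few counts were removed with filterByExpr at its default minimum of 10 counts and 15 counts in total, which left 18098 genes, and 21194 genes had no count in any library. TMM factors, which ran from 0.922 to 1.16, scaled the library sizes. A model with 1 mean per group and 8 residual degrees of freedom was fitted to all 12 libraries with robust quasi-likelihood dispersions (glmQLFit), and glmQLFTest gave 7 contrasts: the diet effect in each genotype, the genotype effect on each diet, their interaction, and both effects averaged. P-values were adjusted by Benjamini and Hochberg over the 18098 genes, and a gene is called at an adjusted p under 0.05. Fold changes are log2, with a prior count of 2 where log CPM is used, SE is the standard error of the fitted log2 fold change, and SD is over 3 libraries. CPM values use TMM library sizes unless raw CPM is named.

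The 30 gene lists held 584 symbols, of which 1 matched no identifier, and 29 lists were tested. They cover liver metabolism, hepatocyte zones and products, sex-biased genes, the other cell types that a liver sample holds, interferon and stress responses, cell death, the clock and the cell cycle. Each was tested with limma 3.58.1 camera at a preset correlation of 0.01 between genes, which asks whether members moved against the other genes, with adjustment over the 29 lists of a comparison. The same test was repeated with a correlation estimated from the residuals, and fry was run as a test of the members alone. No list held its call with an estimated correlation in any of the 7 comparisons, and the adjusted p from that test is given beside each call. For each list the number of members called over all genes is given with the number "adjusted over the list alone".

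The text names Mlkl in every library. It names, per comparison, up to 10 called genes per direction with the largest log2 fold change among those with a mean of at least 5 CPM and no overlap between the groups, in both strata for the averages. It also names up to 4 called members of each list by fold change or, where fewer than 2 were called, up to 2 members with the highest mean CPM, and any called gene within 5 Mb of Mlkl. Genes of the sex check and Nnt complete the rule. Predicted genes without a name were passed over, and some genes that the rule takes are not reported here. The members of the Cyp3a, Serpina1, Gstp and Acot families are near-identical copies, and reads near their 3' ends may be shared between copies, so their single values are uncertain.

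Alternatives were size factors of the RLE type, library size only, no filter beyond 1 count, a filter of 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, dispersions without robust estimation, fits of the compared groups only, a code in the titles as a term, and leaving out each of the 12 libraries. The code follows the diet in each title and its meaning is not given in the sources used here. Codes 23 and 27 stand on ND libraries and 25 and 29 on HFD libraries. Libraries with 23 or 25 are called the lower code level and those with 27 or 29 the higher code level, with 3 libraries of each genotype at each level. Residual correlation between libraries of different groups averaged 0.0127 over the 26 pairs at the same level and -0.0109 over the 28 pairs at different levels. A second sample structure, the level of counts at 8 loci described in the report, was used as a term after the data were seen.

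The scripts were tested on simulated counts for the 18098 genes with 67, 67 and 66 genes changed by folds of 1.5, 2 and 4. At a simulated fold of 4, the share of changed genes recovered was 83.3% for the diet effect in each genotype, 81.8% for genotype on ND, 74.2% for genotype on HFD, 71.2% for the interaction, 86.4% for the diet average and 89.4% for the genotype average. At a fold of 2 the shares were 29.9% for diet in wild-type, 38.8% for diet in Mlkl-/-, 35.8% for genotype on ND, 37.3% for genotype on HFD, 11.9% for the interaction, 68.7% for the diet average and 67.2% for the genotype average. At a fold of 1.5 they were 10.4%, 1.49%, 5.97%, 10.4%, 4.48%, 17.9% and 23.9% in the same order. With nothing changed, 0 to 3 genes were called per comparison. Camera gave a 20-gene list raised 1.5-fold (genotype on HFD) an adjusted p of 1.82e-14 and called 0 unchanged lists. No run with correlated genes is given, so list calls on such genes are unchecked. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.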

Results

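Gene expression was measured in the livers of 12 mice by 3' mRNA sequencing, in which each read stands for the end of 1 polyadenylated transcript. The design crossed genotype with diet in 4 groups of 3 animals: wild-type and Mlkl-/- mice, each fed normal chow (ND) or a high-fat diet (HFD) with 36% fat and 59% of its energy from lipid. MLKL is the pseudokinase that ruptures the plasma membrane in necroptosis, a lytic form of programmed cell death, and the series addresses its part in diet-induced obesity and fatty liver. The sample labels give 25 weeks of diet, whereas the series text gives a range that starts at 16 weeks. Total counts of replicates 1 to 3 were 23477594, 21055761 and 32120426 in the wild-type ND libraries and 22108300, 24356087 and 26535219 in the Mlkl-/- ND libraries. On HFD they were 22494238, 28431749 and 19435391 in wild-type and 20721493, 22365664 and 23610937 in Mlkl-/- livers. Transcripts of the Y-linked genes Ddx3y (1014 to 2731 counts), Kdm5d (196 to 603), Eif2s3y (755 to 1567) and Uty (229 to 584) were found in all 12 libraries, with 0 to 20 counts of Xist, the RNA of the inactive X chromosome. Nnt, a gene that is partly deleted in the C57BL/6J substrain, had 26.8 to 79.9 raw CPM in the 12 libraries.

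Mlkl (ENSMUSG00000012519, chromosome 8, 111311797 to 111338177 on the minus strand of mm10) was lower in all 6 Mlkl-/- libraries than in any wild-type library. On ND it was counted 72, 76 and 92 times in wild-type and 16, 15 and 20 times in Mlkl-/- libraries, a mean of 3.27 ± 0.398 against 0.747 ± 0.0712 CPM (SD, n = 3). On HFD the counts were 134, 252 and 88 in wild-type and 16, 9 and 34 in Mlkl-/- libraries, or 5.75 ± 1.74 against 0.866 ± 0.492 CPM. The log2 difference between genotypes was -2.71 ± 0.36 on HFD (SE; adjusted p = 0.0166), -2.12 on ND (adjusted p = 0.144) and -2.42 ± 0.26 averaged over diets (adjusted p = 0.00202). The position of the deletion is not given in the sources used here, and 3' reads outside a deleted part would check nothing, so the residual counts cannot be read as transcript of an intact gene. Of 77 other tested genes within 5 Mb of Mlkl, 0 were called for genotype by edgeR on ND, on HFD or on average, with 2, 10 and 4 at an unadjusted p under 0.05.

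**Figure D1:**
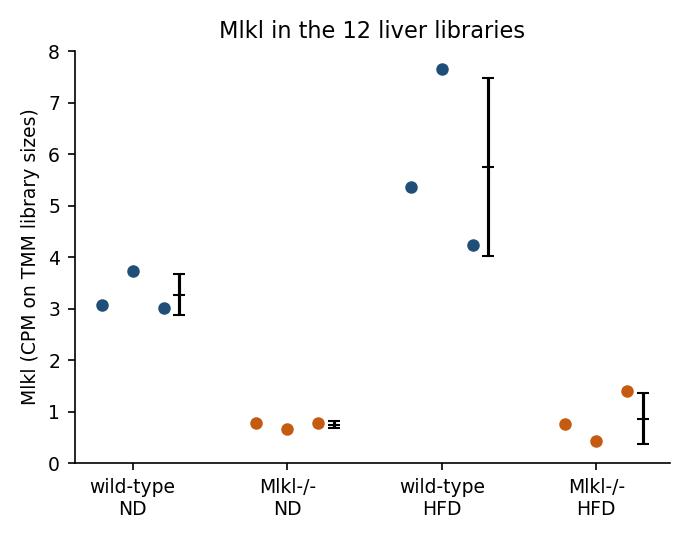
Mlkl in CPM on TMM library sizes (vertical axis) in each of the 12 libraries by group (horizontal axis), with the group mean and SD as a bar beside 3 points per group. The wild-type libraries lie between 3.01 and 7.65 CPM and the Mlkl-/- libraries between 0.433 and 1.40 CPM.

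Libraries also differed in 2 ways that the groups do not give. At 8 loci, namely the annotated small RNAs Mir6236, Gm23935, Gm24270, Gm24187, Gm25911 and Gm24245, the antisense gene Gm15564 and the mitochondrial leucyl-tRNA synthetase gene Lars2, 6 libraries held 3484 to 9239 summed raw CPM and 6 held 378 to 656. The higher level was found in Mlkl-/- ND replicate 1, wild-type HFD replicates 2 and 3 and all 3 Mlkl-/- HFD libraries. Title codes form the other division, with wild-type ND replicates 1 and 2, Mlkl-/- ND replicate 1, wild-type HFD replicate 1 and Mlkl-/- HFD replicates 1 and 2 at the lower code level (animal numbers 859 to 915) and the rest at the higher one (1142 to 1231).

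**Figure D2:**
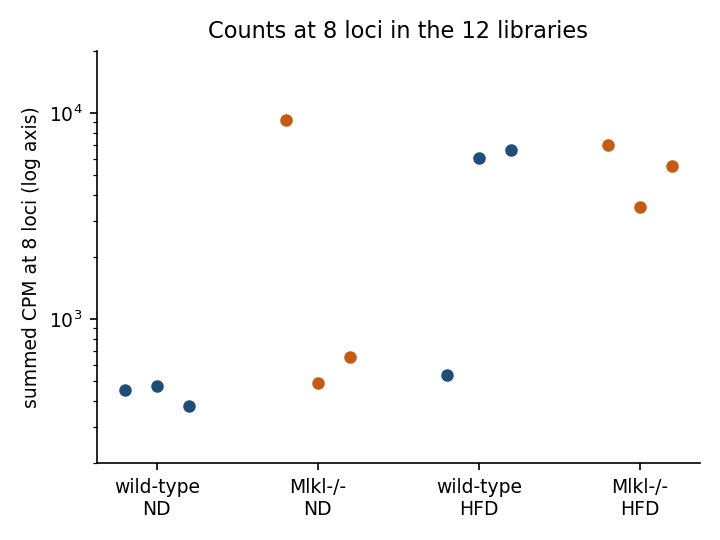
Summed raw CPM at 8 loci (vertical log axis) in each of the 12 libraries by group (horizontal axis). Points fall between 378 and 656 or between 3484 and 9239, and 5 of the 6 libraries at the higher level are from HFD livers.

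HFD against ND in wild-type mice shows the response of livers that have MLKL. Genes of lipid storage and transport were among the risers. Apoa4, an apolipoprotein of triglyceride-rich particles, rose by 4.36 ± 0.62 (log2, SE; adjusted p = 0.00926), from 160 ± 71.0 to 3287 ± 1427 CPM (SD, n = 3). Cidea, which enlarges lipid droplets, rose by 5.16 ± 1.00 (adjusted p = 0.0264), and Osbpl3, a lipid-transfer protein, by 2.96 ± 0.26, from 5.69 ± 1.03 to 44.1 ± 12.5 CPM (adjusted p = 0.00016). Cytochrome P450 genes of the Cyp3a family fell, with Cyp3a11, the main drug-oxidising member, down by 2.69 on the log2 scale (SE 0.49, adjusted p = 0.0188) from 3384 ± 918 to 523 ± 299 CPM. In all, 766 of 18098 genes were called, 366 higher and 400 lower, and 325 of them differed by more than 2-fold.

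Lipid synthesis rose as a group. Of 24 genes of cholesterol synthesis, 14 rose and 0 fell, and 19 rose when adjusted over the list alone, with a median of 0.95 (camera adjusted p = 5.19e-19, and adjusted p = 0.131 with an estimated correlation). Per library the list stood at -0.50 to -0.63 in wild-type ND livers, at -0.06 in wild-type HFD replicate 1 and at 0.68 and 0.43 in replicates 2 and 3, the wild-type libraries at the higher 8-locus level. Over all groups it was higher with that level by a median of 0.50 (adjusted p = 2.08e-16, and adjusted p = 0.160 with an estimated correlation). With the level as a term the diet call held (adjusted p = 5.16e-09). Among its members Mvd rose by 2.01 ± 0.41, Sqle, an oxygenase that limits sterol synthesis, by 1.88 ± 0.44, Hmgcs1 by 1.82 ± 0.39 and Fdps by 1.70 ± 0.25. In fatty acid synthesis 6 of 19 genes rose, or 15 higher and 1 lower adjusted over the list alone (median 1.13, adjusted p = 1.78e-12, and adjusted p = 0.114 with an estimated correlation). Examples were Pnpla3, a lipase-like protein whose human form is tied to fatty liver, at 2.88 ± 0.63, the acetyl-CoA carboxylase Acacb at 2.34 ± 0.38, the elongase Elovl5 at 1.54 ± 0.28 and the desaturase Fads2 at 1.33 ± 0.25. Without wild-type HFD replicate 2, Pnpla3 was not called, at a value of 1.62 and an adjusted p of 0.150. In lipid droplets and lipid uptake 9 of 24 genes rose, led by Cidea, Apoa4, the acyltransferase Mogat1 (3.59 ± 0.60) and the lipoprotein receptor Vldlr (2.09 ± 0.41). Adjusted over the list alone 12 rose, with a median of 0.59 (adjusted p = 6.84e-11, and adjusted p = 0.105 with an estimated correlation). Fatty acid oxidation had 1 riser among 27 genes, the PPAR-alpha target Vnn1 (1.83 ± 0.43), and 11 adjusted over the list alone (median 0.38, adjusted p = 6.32e-06, and adjusted p = 0.245 with an estimated correlation). Pcx, pyruvate carboxylase, rose by 0.95 ± 0.16 and was the 1 called gene of 16 in glucose metabolism (median 0.06, mean -0.09, adjusted p = 0.834).

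Macrophage and interferon-stimulated genes rose as lists. Of 24 genes of monocyte-derived and lipid-associated macrophages 5 rose, among them Gpnmb (4.14 ± 0.78), the elastase Mmp12 (3.66 ± 0.70), the monocyte chemokine Ccl2 (3.13 ± 0.83) and the fractalkine receptor Cx3cr1 (2.15 ± 0.47). Adjusted over the list alone 10 rose, with a median of 0.79 (adjusted p = 3.88e-09, and adjusted p = 0.245 with an estimated correlation). Gpnmb, Ccl2 and Cx3cr1 were low in the ND livers, at 0.252 ± 0.169, 0.167 ± 0.113 and 0.470 ± 0.159 CPM. Interferon-stimulated genes rose in 9 of 33 cases, or 21 adjusted over the list alone (median 0.70, adjusted p = 5.13e-17, and adjusted p = 0.105 with an estimated correlation). Usp18, a brake on interferon signalling, stood at 2.05 ± 0.31, Ifit2 at 1.62 ± 0.32 and Oas1a at 1.48 ± 0.31. In fibrosis and stellate cells 1 of 22 genes rose, the proteoglycan Lum (1.20 ± 0.23), and 5 adjusted over the list alone, with a median of 0.75 (adjusted p = 1.13e-06, and adjusted p = 0.319 with an estimated correlation). Kupffer cell genes had 0 called of 15 and 0 adjusted over the list alone, with a median of 0.41 (adjusted p = 0.00165, and adjusted p = 0.481 with an estimated correlation). Sinusoidal endothelial genes had 1, the nuclease Dnase1l3 (0.60 ± 0.15), of 14, with a median of 0.25 (adjusted p = 0.0265, adjusted p = 0.577 with an estimated correlation, and adjusted p = 0.452 and 0.309 without wild-type HFD replicate 1 and wild-type ND replicate 3). The mean of these endothelial, stellate and macrophage genes per library, as a deviation from each gene's mean, was 0.85 and 0.80 in wild-type HFD replicates 1 and 2 and 0.01 in replicate 3. Adipose tissue genes had 1 riser of 8, hormone-sensitive lipase Lipe (1.18 ± 0.23), or 3 adjusted over the list alone (median 1.09, adjusted p = 0.0393, and adjusted p = 0.472 with an estimated correlation). Adipoq, the adipocyte hormone, was at 0.0801 CPM in wild-type HFD replicate 1 and at 3.13 and 3.33 CPM in replicates 2 and 3. With the 8-locus level as a term the adipose list turned direction, at adjusted p = 0.905. Its call also ended with library size in place of TMM (adjusted p = 0.146), with the title code as a term (0.128) and with the code level fitted within each genotype (0.306). It ended too without wild-type HFD replicates 2 or 3 (adjusted p = 0.0542 and 0.456), wild-type ND replicates 1 or 3 (0.117 and 0.0555), Mlkl-/- ND replicate 1 (0.0536) or Mlkl-/- HFD replicate 2 (0.0558).

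Products of hepatocytes fell. Of 20 genes of secreted hepatocyte proteins 8 fell, or 13 adjusted over the list alone, with a median of -0.53 (adjusted p = 3.88e-09, and adjusted p = 0.105 with an estimated correlation). Among them were the antitrypsin genes Serpina1c (-1.35 ± 0.23) and Serpina1a (-1.22 ± 0.22) and the fibrinogen chain Fgb (-1.21 ± 0.25). Ribosomal protein genes fell in 10 of 28 cases, or 24 adjusted over the list alone (median -0.57, adjusted p = 2.91e-17, and adjusted p = 0.245 with an estimated correlation). Rps27 stood at -1.10 ± 0.16 and Rpl41 at -0.88 ± 0.17. Male-biased genes fell as a list with a median of -0.66 (2 of 18 called and 2 adjusted over the list alone, adjusted p = 2.14e-08, and adjusted p = 0.245 with an estimated correlation). The called members were Serpina1e (-3.08 ± 0.45, from 11763 ± 911 to 1394 ± 434 CPM) and the glutathione transferase Gstp2 (-1.91 ± 0.27), and its neighbour Gstp1 fell by 1.78 on the log2 scale. The male-biased list stood at -1.96 and -2.16 in wild-type HFD replicates 1 and 2 but at 0.16 in replicate 3. Female-biased genes had 3 fallers of 14, all of the Cyp3a family, such as Cyp3a44 (-2.75 ± 0.57) and Cyp3a41a (-2.71 ± 0.52), while the list's median was 0.64 and its test pointed down (adjusted p = 0.617). Xenobiotic metabolism had 2 risers, such as Gstm2 (1.19 ± 0.23), and 5 fallers of 25, such as Cyp3a25 (-1.19 ± 0.19), with a median of 0.12, a mean of 0.32 and a test that pointed down (adjusted p = 0.459). Pericentral hepatocyte genes rose in 5 of 15 cases and fell in 1, as with glutamine synthetase Glul at 1.56 ± 0.27 and the Wnt target Axin2 at 1.29 ± 0.29 (median 0.45, adjusted p = 0.000753, and adjusted p = 0.245 with an estimated correlation). That call ended with the 8-locus level as a term (adjusted p = 0.0719). Periportal genes fell as a list with a median of -0.70 (1 of 17 called, Sdsl, and 7 adjusted over the list alone, adjusted p = 1.88e-06, and adjusted p = 0.245 with an estimated correlation).

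Other risers were Themis (3.74 ± 0.69), which acts in T cell development, the sphingomyelinase Smpd3 (2.77 ± 0.57), Tlr12 (2.73 ± 0.56), the heparan sulfate proteoglycan Gpc1 (2.32 ± 0.29) and Anxa2 (2.11 ± 0.47). Asparagine synthetase Asns (-4.54 ± 0.95), the retinoic acid hydroxylase Cyp26a1 (-2.87 ± 0.68) and the carboxylesterase Ces2a (-2.27 ± 0.28) were among the fallers. Asns is a target of Atf4, which fell by 0.51 on the log2 scale, and both are among the 2 fallers of 23 stress-response genes (median -0.22, adjusted p = 0.0646). Hamp, the iron hormone hepcidin (-1.69 ± 0.41), Itih3 (-1.06 ± 0.26) and Saa4 (-0.85 ± 0.18) fell within the acute phase list, which had 3 fallers of 17 (median -0.33, adjusted p = 0.0644). Tnfaip3 (1.32 ± 0.25) was the called gene of 31 in cell death (median 0.20, adjusted p = 0.0767) and Anxa5 (1.73 ± 0.31) that of 12 in cholangiocytes (median 0.30, adjusted p = 0.0796). In red blood cells it was the haem enzyme gene Alas2 (-1.01 ± 0.22) of 5 (median -0.07, adjusted p = 0.228). In bile acid synthesis and transport 2 of 21 genes rose (median -0.03, adjusted p = 0.662). Lists without a gene called by edgeR or a call by camera were lymphocytes (median -0.33, adjusted p = 0.355), neutrophils (0.44, adjusted p = 0.244), pancreas (-0.66, 3 genes, adjusted p = 0.105, but 0.0418 by fry), circadian clock (0.12, adjusted p = 0.513) and cell cycle (0.19, adjusted p = 0.0858).

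The number of called genes moved from 766 to 198, 100 and 113 without wild-type ND replicates 1, 2 and 3, to 359 and 63 without wild-type HFD replicates 1 and 2, and to 1233 without Mlkl-/- ND replicate 1. It was 158 with the 8-locus level as a term, when 20 of the 56 called genes named here kept their call. Fdps was then at 1.13 and still called (adjusted p = 0.00943), while Mvd (1.28), Sqle (0.93), Lipe (0.78), Hamp (-0.87) and Sdsl (-0.62) were not (adjusted p = 0.0807, 0.119, 0.0839, 0.0807 and 0.179). Glul, at 1.00, stayed called too (adjusted p = 0.0385). With the title code as a term 44 of the 56 kept their call, and 46 with it fitted within each genotype. In the leave-one-out fits 12 of the 56, Osbpl3, Fdps, Usp18, Apoa4, Gpc1 and Rps27 among them, kept it in each of the 12 fits without 1 library.

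HFD against ND in Mlkl-/- mice shows the response of livers without the gene. Osbpl3 again rose, by 2.60 ± 0.27 (log2, SE; adjusted p = 0.000832), from 2.69 ± 0.956 to 16.2 ± 2.74 CPM (SD, n = 3). Fabp2, a fatty acid binding protein, rose by 1.68 ± 0.18 (adjusted p = 0.000832), from 49.5 ± 8.96 to 158 ± 33.6 CPM, and Vldlr by 3.38 ± 0.48 (adjusted p = 0.00654). Pltp, the phospholipid transfer protein of plasma, rose by 2.50 ± 0.29 (adjusted p = 0.00536). Cyp3a11 fell by 3.14 on the log2 scale (SE 0.50, adjusted p = 0.0352), from 2924 ± 1036 to 331 ± 127 CPM. In all 65 genes were called, 38 higher and 27 lower.

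Fatty acid oxidation rose as a list with a median of 0.48. In it 2 of 27 members were called, the thioesterases Acot2 and Acot1 (1.46 ± 0.26), and 14 adjusted over the list alone. Camera gave adjusted p = 1.16e-14 for it, and adjusted p = 0.147 with an estimated correlation. Lipid droplet and uptake genes rose with a median of 0.63 (Fabp2 and Vldlr called of 24, and 10 adjusted over the list alone, adjusted p = 1.16e-14, and adjusted p = 0.147 with an estimated correlation). Fatty acid synthesis rose with a median of 0.84 (1 of 19 called, the desaturase Fads1 at 1.25 ± 0.17, and 8 adjusted over the list alone, adjusted p = 8.64e-12, and adjusted p = 0.147 with an estimated correlation). Cholesterol synthesis had 0 called of 24 and 0 adjusted over the list alone, with a median of 0.20 (adjusted p = 0.0503). Other risers were Sulf2, an editor of heparan sulfate (1.55 ± 0.19), the lysolipid transporter Mfsd2a (1.68 ± 0.27), the water channel Aqp4 (2.03 ± 0.36), Adgrv1, Acot5, Tmem86a and Gpc1 (2.28 ± 0.29). Fallers were Cyp3a41b (-3.26 ± 0.54), Cyp3a59, Cyp3a25 (-1.28 ± 0.19), Ces2a (-1.63 ± 0.28), histidine decarboxylase Hdc (-1.64 ± 0.25), the caveolin Cav2 (-1.51 ± 0.30) and the chaperone Dnajb9 (-1.13 ± 0.20). Lipe (1.19 ± 0.23) was the called member of the adipose list (1 of 8, and 1 adjusted over the list alone, median 2.14, adjusted p = 0.000243, and adjusted p = 0.515 with an estimated correlation). The list's mean deviation per library was -0.87 in Mlkl-/- HFD replicate 1 and 0.86 and 0.69 in replicates 2 and 3. With the 8-locus level as a term the adipose adjusted p was 0.0977.

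Sinusoidal endothelial genes fell as a list on HFD, with 0 of 14 called but 8 lower adjusted over the list alone (median -0.54, adjusted p = 1.58e-07, and adjusted p = 0.532 with an estimated correlation). Kupffer cell genes fell with a median of -0.37 (0 of 15 called and 0 adjusted over the list alone, adjusted p = 0.000801, and adjusted p = 0.608 with an estimated correlation). That list stood at adjusted p = 0.0880 without Mlkl-/- HFD replicate 2 and 0.823 with the 8-locus level as a term. Male-biased genes (median -0.60, adjusted p = 0.00656) and ribosomal protein genes (-0.26, adjusted p = 4.23e-05) fell with 0 members called, both at adjusted p = 0.608 with an estimated correlation. Adjusted over the list alone, 1 male-biased gene was higher and 2 were lower, and 2 ribosomal protein genes were lower. Cholangiocyte genes (-0.67, adjusted p = 0.0320) fell with 0 called and the stress response (-0.14, adjusted p = 0.0273) with 1, Dnajb9, both at adjusted p = 0.597 with an estimated correlation. Interferon-stimulated genes rose with a median of 0.18 and 0 of 33 called (adjusted p = 0.00351, and adjusted p = 0.597 with an estimated correlation). Without Mlkl-/- ND replicate 1 the ribosomal, interferon, male-biased and cholangiocyte calls ended (adjusted p = 0.210, 0.150, 0.0692 and 0.158). The male-biased call also ended without Mlkl-/- HFD replicate 3 (0.103), the cholangiocyte call without Mlkl-/- HFD replicate 2 (0.225) and the stress-response call without Mlkl-/- ND replicate 2 or Mlkl-/- HFD replicate 2 (0.0864 and 0.179). Lymphocyte genes had a median of 0.78 (0 of 17 called, adjusted p = 0.0339, and adjusted p = 0.608 with an estimated correlation). Its call held without wild-type ND replicate 1, Mlkl-/- ND replicate 3 or Mlkl-/- HFD replicate 1 and ended in the other 9 fits without 1 library. The list turned direction without Mlkl-/- HFD replicate 2 (adjusted p = 0.985), where the immunoglobulin genes Ighm and Igkc stood at 125 and 58.1 CPM. The lymphocyte call also ended with library size in place of TMM (0.102), the 8-locus level (0.0586), the title code (0.0544) or the code within each genotype (0.0576). With the code within each genotype the Kupffer, cholangiocyte and stress-response calls ended as well (0.0659, 0.0598 and 0.0895), the last also with the title code alone (0.0681). Fibrosis (-0.27, adjusted p = 0.0751), macrophage (-0.17, adjusted p = 0.241) and secreted hepatocyte genes (-0.14, adjusted p = 0.0560) were not called as lists.

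The count of 65 moved to 729 without Mlkl-/- ND replicate 1, to 97 without Mlkl-/- HFD replicate 2 and to 13, 15, 27 and 28 without Mlkl-/- ND replicate 3, Mlkl-/- HFD replicate 1, Mlkl-/- ND replicate 2 and wild-type HFD replicate 1. It was also lower without wild-type ND replicates 1 and 2 (37 and 42) and wild-type HFD replicate 2 (43), and it was 27 with the 8-locus level as a term. Of the 23 called genes named here, 11 kept their call with that term, 16 with the title code and 13 with the code within each genotype, and 8 kept their call in all 12 fits without 1 library, among them Osbpl3, Fabp2, Sulf2 and Pltp.

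The diet responses of both genotypes were then set side by side across genes, which are not independent replicates. Log2 fold changes had a Pearson r of 0.285 and a Spearman rho of 0.234 over the 18098 genes, and 0.758 and 0.739 over the 794 genes called in either genotype. Of the 766 genes called in wild-type, 669 had the same sign in Mlkl-/- mice. Both genotypes called 21 higher genes, against 0.768 for independent lists, and 16 lower genes, against 0.597. Osbpl3, Gpc1, Cyp3a11, Cyp3a25, Ces2a, Lipe and Vldlr are among the genes called in both. No library is shared by the 2 contrasts. The interaction below tests whether responses differ between genotypes.

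**Figure D3:**
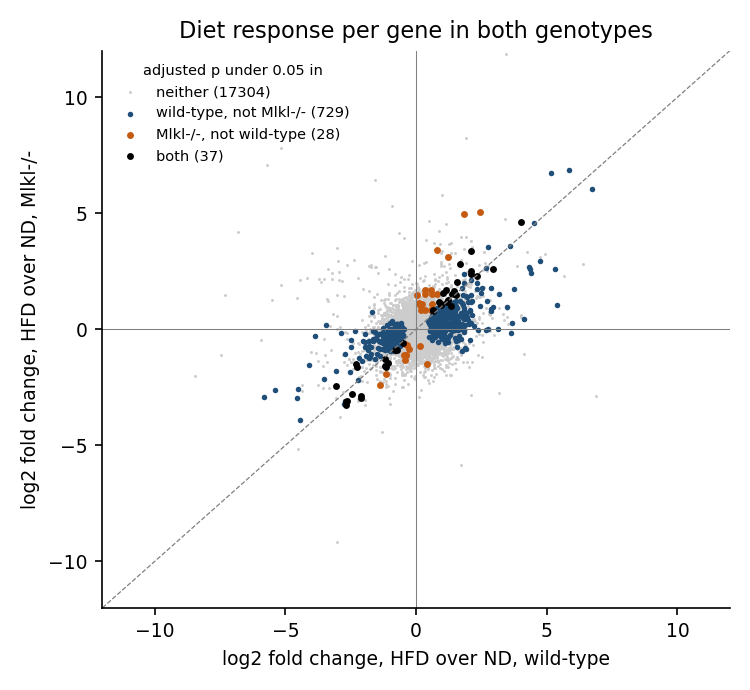
Log2 fold change of HFD over ND per gene in wild-type (horizontal) and in Mlkl-/- mice (vertical) for 18098 genes, coloured by where the adjusted p is under 0.05, with the diagonal dashed. Pearson r is 0.285 over all genes and 0.758 over the 794 genes called in either genotype.

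Mlkl-/- against wild-type on ND shows the effect of the gene without the dietary challenge. Mybph, a myosin-binding protein, fell by 1.53 on the log2 scale (SE 0.19, adjusted p = 0.0193), from 8.47 ± 1.29 to 2.93 ± 0.211 CPM (SD, n = 3), and was the 1 gene called. Its call ended without wild-type ND replicates 2 or 3, any of the 3 Mlkl-/- ND libraries, wild-type HFD replicate 1 or Mlkl-/- HFD replicate 1, with a highest adjusted p of 0.248. At an unadjusted p under 0.05 stood 997 genes, near the 904.9 that chance gives, DESeq2 called 45 genes and limma-voom 0. Cholesterol synthesis rose as a list with a median of 0.51, with 0 of 24 members called and 9 higher adjusted over the list alone (adjusted p = 7.35e-18, and adjusted p = 0.340 with an estimated correlation). Cholesterol genes moved with the 8-locus level too: the list stood at 0.34 in Mlkl-/- ND replicate 1, the ND library at the higher level, and at -0.03 and -0.25 in the other 2, against -0.50 to -0.63 in the wild-type ND libraries.

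Genes of fat metabolism fell as lists on ND with 0 members called. Fatty acid oxidation had a median of -0.26 and 3 members lower adjusted over the list alone (adjusted p = 6.71e-11, and adjusted p = 0.340 with an estimated correlation). Lipid droplet and uptake genes had a median of -0.41 and 1 lower adjusted over the list alone (adjusted p = 1.21e-06, and adjusted p = 0.340 with an estimated correlation). Fatty acid synthesis had a median of -0.36 and 1 lower adjusted over the list alone (adjusted p = 7.43e-06, and adjusted p = 0.418 with an estimated correlation). Scd1, the stearoyl-CoA desaturase, was at 8814 ± 1692 in wild-type and 4054 ± 947 CPM in Mlkl-/- livers, a log2 difference of -1.12 ± 0.28 that missed the threshold (adjusted p = 0.431). The droplet coat gene Plin2 differed by -0.57 (adjusted p = 0.925). Acute phase genes rose as a list with a median of 0.64, with 2 higher and 1 lower adjusted over the list alone (adjusted p = 3.88e-08, and adjusted p = 0.418 with an estimated correlation). Its most abundant members, haptoglobin Hp (0.61) and Itih4 (0.64), were not called (adjusted p = 0.816 and 0.893). Hp lies within 5 Mb of Mlkl. Interferon-stimulated genes (median 0.20, adjusted p = 0.000392) and stress-response genes (0.08, adjusted p = 0.00828) rose as lists, at adjusted p = 0.521 and 0.461 with an estimated correlation. Adipose genes fell (-1.52, adjusted p = 0.000914, and adjusted p = 0.440 with an estimated correlation). Weaker list calls were male-biased (0.28) and cholangiocyte genes (0.26) upward and female-biased genes (-0.23) downward, each at adjusted p = 0.0412 and at adjusted p = 0.684 with an estimated correlation. Krt8 and Krt18, keratins of hepatocytes and bile ducts, reached 1010 and 459 CPM in Mlkl-/- ND replicate 1, against 174 to 212 and 140 to 154 CPM in wild-type ND libraries, and were not called (1.49 and 1.04, adjusted p = 0.624 and 0.476). Lymphocyte genes (-0.74, adjusted p = 0.0361) and sinusoidal endothelial genes (-0.15, adjusted p = 0.0264) were also called, both at adjusted p = 0.684 with an estimated correlation. The lymphocyte call ended in 8 of the 12 fits without 1 library, up to an adjusted p of 0.976 without wild-type ND replicate 1, and the endothelial one without wild-type ND replicates 1 or 2 or Mlkl-/- ND replicate 1 (0.382, 0.138 and 0.624). Male-biased, cholangiocyte and female-biased calls ended in 5, 6 and 3 of these fits, with highest adjusted p of 0.196, 0.253 and 0.591 without wild-type ND replicate 1, wild-type ND replicate 3 and Mlkl-/- ND replicate 3. The interferon call ended without Mlkl-/- ND replicate 3 (0.163) and the stress-response call without wild-type ND replicate 2 or Mlkl-/- ND replicate 2 (0.111 and 0.0849). With the 8-locus level as a term the endothelial, male-biased, cholangiocyte and lymphocyte calls ended (adjusted p = 0.820, 0.309, 0.0985 and 0.0571). The title code as a term ended the endothelial (0.0663), lymphocyte (0.0835), male-biased and female-biased calls (0.0512 for both). Fitted within each genotype it ended the lymphocyte (0.133), male-biased (0.102), cholangiocyte (0.0822), female-biased and stress-response calls (0.0557 for both), and library size in place of TMM ended the lymphocyte and female-biased calls (0.0972 for both).

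Mlkl-/- against wild-type on HFD is closest to the title of the series. Genes of the sinusoidal endothelium were lower in Mlkl-/- livers. Dnase1l3 fell by 1.17 on the log2 scale (SE 0.15, adjusted p = 0.0166), from 38.3 ± 2.06 to 17.0 ± 2.53 CPM (SD, n = 3). Fcgr2b, the inhibitory Fc receptor of these cells, fell by 1.21 (SE 0.18, adjusted p = 0.0353), from 45.3 ± 9.89 to 19.5 ± 2.28 CPM. Flt4, a VEGF receptor, fell by 1.62 (SE 0.25, adjusted p = 0.0424), from 25.6 ± 4.48 to 8.34 ± 1.63 CPM. Saa4, the constitutive serum amyloid A, rose by 1.31 ± 0.18 (adjusted p = 0.0201), from 176 ± 39.6 to 436 ± 74.5 CPM. With Mlkl itself these made 5 called genes, while 2806 stood at an unadjusted p under 0.05.

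Markers of several cells other than hepatocytes fell together on HFD. Of 14 sinusoidal endothelial genes 2 were called and 12 were lower adjusted over the list alone, with a median of -0.94 (adjusted p = 1.33e-22, and adjusted p = 0.152 with an estimated correlation). Fibrosis and stellate cell genes had 0 of 22 called but 16 lower adjusted over the list alone (median -1.01, adjusted p = 7.53e-13, and adjusted p = 0.279 with an estimated correlation). Their abundant members, the matrix proteoglycans Dcn (-0.48) and Bgn (-0.54), missed the threshold (adjusted p = 0.210 and 0.256). Kupffer cell genes had 12 of 15 lower adjusted over the list alone (median -0.86, adjusted p = 3.25e-11, and adjusted p = 0.279 with an estimated correlation). Clec4f, the lectin of Kupffer cells, was at 88.5 ± 17.7 in wild-type and 47.5 ± 16.3 CPM in Mlkl-/- (-0.90, adjusted p = 0.163). Monocyte-derived and lipid-associated macrophage genes had 10 of 24 lower adjusted over the list alone (median -0.92, adjusted p = 4.41e-11, and adjusted p = 0.279 with an estimated correlation). Lysozyme, Lyz2, differed by -0.83 (adjusted p = 0.157). Interferon-stimulated genes fell with a median of -0.34 (0 of 33 called, 3 lower adjusted over the list alone, adjusted p = 0.000264, and adjusted p = 0.338 with an estimated correlation). Cholangiocyte genes fell with a median of -0.67 (1 lower adjusted over the list alone, adjusted p = 0.00706, and adjusted p = 0.338 with an estimated correlation). That call ended without wild-type HFD replicate 2 or Mlkl-/- HFD replicate 2 (adjusted p = 0.0772 and 0.0579). Per library, the 75 endothelial, stellate and macrophage genes stood at 0.85, 0.80 and 0.01 in wild-type HFD replicates 1 to 3 and at -0.71, -0.40 and -0.00384 in Mlkl-/- HFD replicates 1 to 3. Their median difference was -0.90 over all HFD libraries. In those of 1 code level alone it was -1.38 at the lower (1 wild-type and 2 Mlkl-/-) and -0.46 at the higher one (2 and 1).

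**Figure D4:**
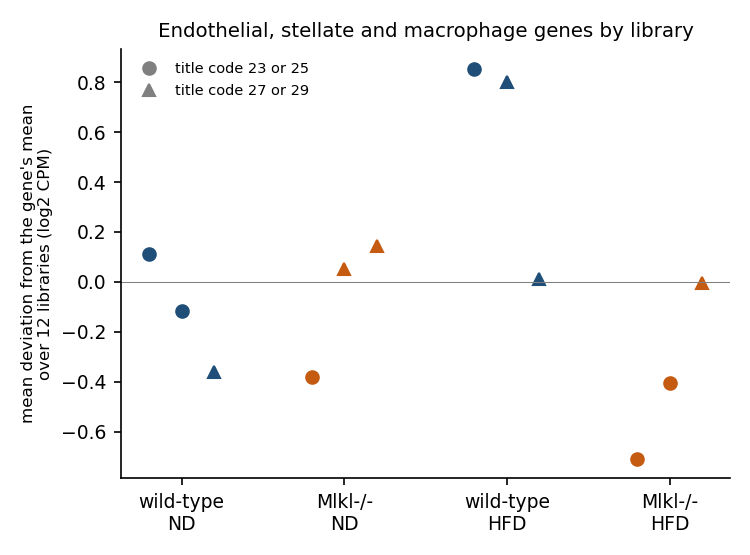
Mean deviation of 75 endothelial, stellate and macrophage genes from each gene's mean over the 12 libraries (log2 CPM, vertical axis) by group (horizontal axis), with circles for title codes 23 or 25 and triangles for 27 or 29. Wild-type HFD replicates 1 and 2 stand at 0.85 and 0.80, and Mlkl-/- HFD replicates 1 and 2 at -0.71 and -0.40.

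Lists of hepatocyte products rose in Mlkl-/- livers on HFD. Genes of secreted proteins had 0 of 20 called and 9 higher adjusted over the list alone (median 0.42, adjusted p = 6.22e-07, and adjusted p = 0.152 with an estimated correlation). Male-biased genes rose with a median of 0.98 and 3 of 18 higher adjusted over the list alone (adjusted p = 1.52e-07, and adjusted p = 0.298 with an estimated correlation). Per library the list stood at -1.96, -2.16 and 0.16 in wild-type HFD replicates 1 to 3 and at -0.38, 0.88 and -0.09 in the Mlkl-/- ones, so wild-type replicate 3 lay above 2 of them. Their abundant members were not called over all genes, with the major urinary protein Mup20 at 5656 ± 2550 in wild-type and 10879 ± 3704 CPM in Mlkl-/- (0.94, adjusted p = 0.179) and Serpina1e at 1.52 (adjusted p = 0.164). Acute phase genes rose with a median of 0.81, with Saa4 called of 17 and 2 higher adjusted over the list alone. Adjusted p was 3.19e-07, and 0.298 with an estimated correlation. By code level the HFD medians were 0.16 (lower) and 1.46 (higher). Mlkl-/- replicate 2 (-0.41) lay below wild-type replicate 1 (-0.28). Hp of that list differed by 0.66 (adjusted p = 0.240). Ribosomal protein genes (0 of 28 called, 2 higher adjusted over the list alone) and periportal genes rose with medians of 0.34 and 0.50. Their adjusted p was 4.77e-09 and 0.000331, and 0.338 for both with an estimated correlation. Pancreas genes, 3 of them, had a median of 0.84 (adjusted p = 0.0195, 0.279 with an estimated correlation and 0.0524 without wild-type HFD replicate 1).

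Lists of lipid metabolism were lower in Mlkl-/- livers on HFD, with 0 members called. Fatty acid synthesis fell with a median of -0.66 (adjusted p = 1.11e-06, and adjusted p = 0.279 with an estimated correlation), with Scd1 at 17257 ± 5754 in wild-type and 8945 ± 2840 CPM in Mlkl-/- (-0.95, adjusted p = 0.164). Lipid droplet and uptake genes fell with a median of -0.32 and 3 of 24 lower adjusted over the list alone (adjusted p = 0.000405, and adjusted p = 0.299 with an estimated correlation). Fatty acid oxidation (-0.18, adjusted p = 0.0195) and female-biased genes (-0.68, adjusted p = 0.0481) were also called downward, both at adjusted p = 0.468 with an estimated correlation. The oxidation call ended without wild-type HFD replicate 3 or Mlkl-/- HFD replicates 2 or 3 (0.209, 0.217 and 0.115), the female-biased one in 8 of the 12 fits without 1 library, up to 0.225 without Mlkl-/- HFD replicate 2, and with the 8-locus level as a term (0.0561) or library size in place of TMM (0.206). Cholesterol synthesis was not called (-0.16, adjusted p = 0.0717), nor were xenobiotic metabolism (-0.43, adjusted p = 0.0595), lymphocytes (0.46, adjusted p = 0.107) or the cell death pathways, to which MLKL belongs (-0.02, 0 of 31, adjusted p = 0.358).

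All 5 calls ended without wild-type HFD replicates 1 or 2 or Mlkl-/- HFD replicate 1 (0 genes). The count was 1 and 2 without Mlkl-/- HFD replicate 2 and wild-type ND replicate 2. It was 189, 75, 21 and 8 without wild-type HFD replicate 3, Mlkl-/- ND replicate 1, Mlkl-/- HFD replicate 3 and Mlkl-/- ND replicate 2. Fitting the code level within each genotype gave 143 (23 higher, 120 lower). By code level, lower calls came only at the lower one, with 1 wild-type HFD animal. That animal is at the lower 8-locus level and Mlkl-/- HFD replicates 1 and 2 are at the higher one, so genotype and 8-locus level are not separated there. With the title code as a term the Fcgr2b and Flt4 calls ended (adjusted p = 0.0638 and 0.0825).

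**Figure D5:**
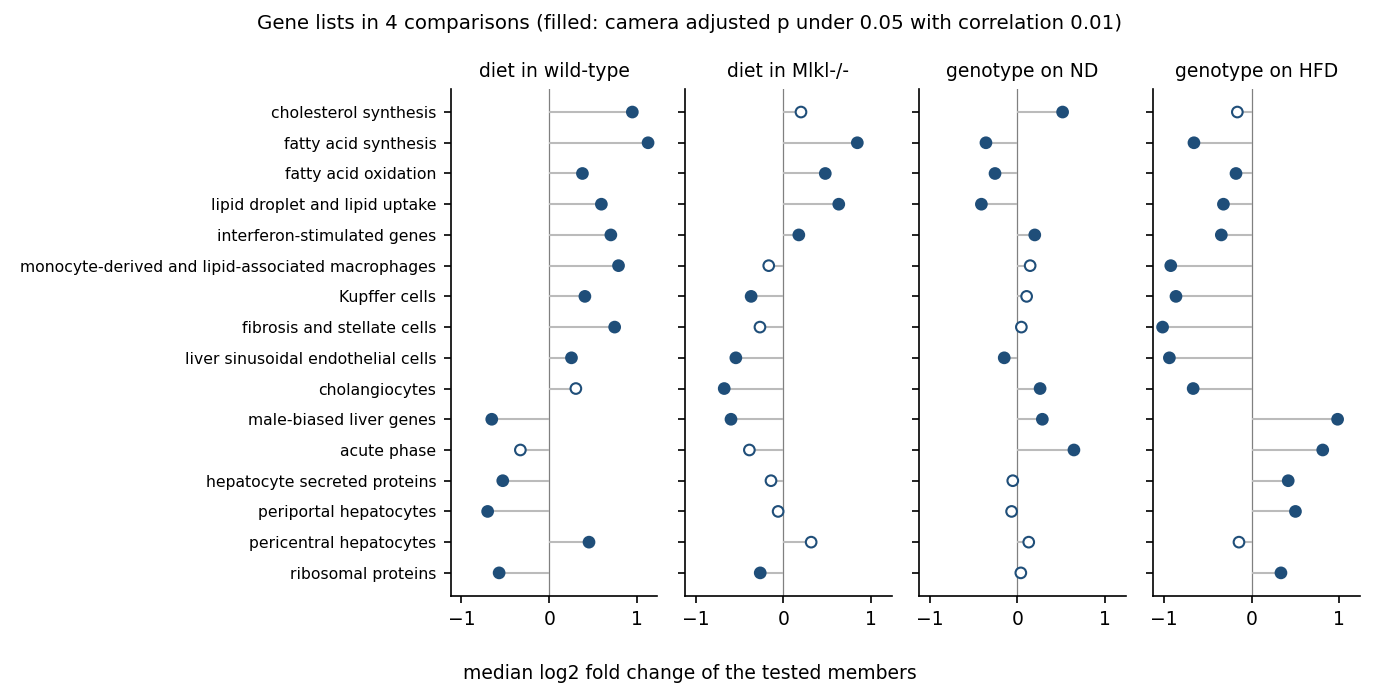
Median log2 fold change of the tested members (horizontal axis) of 16 gene lists (vertical axis) in 4 comparisons, filled where camera with a correlation of 0.01 gave an adjusted p under 0.05. Sinusoidal endothelial genes stand at 0.25 for diet in wild-type, -0.54 for diet in Mlkl-/-, -0.15 for genotype on ND and -0.94 for genotype on HFD, and 0 lists were called with an estimated correlation.

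The interaction of diet and genotype asks whether the response to HFD differed between genotypes. No gene was called by edgeR (0 of 18098, smallest adjusted p = 0.338), with 1889 at an unadjusted p under 0.05, 0 called by limma-voom and 48 by DESeq2. There were 4 called genes without Mlkl-/- ND replicate 1 and 1 without wild-type HFD replicate 3. The water channel Aqp1, an abundant endothelial gene, had an interaction of -0.94 ± 0.26 (adjusted p = 0.370), with means of 65.1 ± 12.3 and 85.1 ± 11.0 CPM on ND and HFD in wild-type and 56.6 ± 5.06 and 38.5 ± 9.89 CPM in Mlkl-/- (SD, n = 3). Clec4f (-0.96, adjusted p = 0.421), Lyz2 (-0.99, adjusted p = 0.407), Krt8 (-1.92, adjusted p = 0.404) and Krt18 (-1.30, adjusted p = 0.384) were not called either. Lists were. Diet effects in Mlkl-/- lay below those in wild-type by a median of -1.10 for monocyte-derived macrophages (11 of 24 lower adjusted over the list alone, adjusted p = 4.42e-11) and -0.86 for sinusoidal endothelium (8 of 14, adjusted p = 7.86e-11). For fibrosis and stellate cells the median was -1.05 (5 of 22, adjusted p = 1.52e-09) and for Kupffer cells -0.91 (0 of 15, adjusted p = 3.95e-09). It was -0.71 for cholesterol synthesis (11 of 24, adjusted p = 3.97e-11) and -0.39 for interferon-stimulated genes (8 of 33, adjusted p = 1.20e-07). Each of these 6 lists had adjusted p = 0.280 with an estimated correlation and 0 members called over all genes. Median, mean and test differed in sign for the acute phase list (-0.00, -0.03 and upward), the stress response (0.01, 0.06 and downward) and the cell cycle (0.03, -0.03 and downward), none of which was called.

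The diet effect averaged over genotypes sets 6 HFD libraries against 6 ND libraries. Osbpl3 rose by 2.78 ± 0.18 (log2, SE; adjusted p = 4.31e-06), Gpc1 and Pltp each by 2.30 ± 0.20 and Fads1 by 1.24 ± 0.12 (adjusted p = 0.000133 for each). Among the strongest risers were Cidea (5.94 ± 0.84), Mogat1 (3.59 ± 0.45), Apoa4 (3.48 ± 0.42), Vldlr (2.73 ± 0.31), the fatty acid hydroxylase Cyp4a14 (2.65 ± 0.43) and the steroid hydroxylase Cyp17a1 (2.35 ± 0.36), with adjusted p from 0.000409 to 0.00872. Fallers included Asns (-3.76 ± 0.63), Cyp3a16 (-3.36 ± 0.50), Cyp3a11 (-2.92 ± 0.35), Serpina1e (-2.44 ± 0.31), the secreted peptide gene Enho (-2.41 ± 0.55) and Gstp2 (-1.53 ± 0.19). In all 1302 genes were called, 646 higher and 656 lower. Without a library the count was 616 to 2029, and it moved by over 1.5 times without wild-type ND replicates 1, 2 or 3 (807, 710 and 705), Mlkl-/- ND replicates 1 or 2 (2029 and 643), wild-type HFD replicate 2 (616) and Mlkl-/- HFD replicates 1 or 3 (660 and 804). With the 8-locus level as a term it was 122, with 13 of the 33 called genes named here still called (25 with the code level fitted within each genotype), Osbpl3, Gpc1, Fads1, Vldlr, Apoa4 and Cyp3a11 among them.

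Of 24 lipid droplet and uptake genes 12 rose, or 13 adjusted over the list alone (median 0.50, adjusted p = 1.08e-17, and adjusted p = 0.0883 with an estimated correlation). Fatty acid synthesis had 8 of 19, or 18 adjusted over the list alone (0.98, adjusted p = 2.48e-17, and adjusted p = 0.0890 with an estimated correlation), and Elovl5 rose by 1.38 ± 0.19. Fatty acid oxidation had 13 of 27, or 16 adjusted over the list alone (0.43, adjusted p = 2.18e-13, and adjusted p = 0.104 with an estimated correlation), with the kinase Pdk4 at 1.87 ± 0.40 and Acot2 at 1.15 ± 0.17. Cholesterol synthesis had 10 of 24, or 18 adjusted over the list alone (0.49, adjusted p = 5.32e-13, and adjusted p = 0.248 with an estimated correlation). Interferon-stimulated genes had 11 of 33, or 19 adjusted over the list alone (0.40, adjusted p = 3.17e-13, and adjusted p = 0.104 with an estimated correlation). Ribosomal protein genes fell in 20 of 28 cases, or 24 adjusted over the list alone (-0.43, adjusted p = 1.95e-15, and adjusted p = 0.276 with an estimated correlation). Secreted hepatocyte proteins fell in 8 of 20, or 10 adjusted over the list alone (-0.31, adjusted p = 5.87e-07, and adjusted p = 0.0999 with an estimated correlation). Male-biased genes fell with a median of -0.74 (2 of 18, adjusted p = 1.28e-07, and adjusted p = 0.276 with an estimated correlation). Macrophage genes (0.41, adjusted p = 0.00191) rose at adjusted p = 0.585 with an estimated correlation, fibrosis genes (0.21, adjusted p = 0.0498) rose at adjusted p = 0.725 with an estimated correlation. The stress response (-0.18, adjusted p = 0.0115) fell at adjusted p = 0.369 with an estimated correlation. The macrophage call ended without Mlkl-/- ND replicate 1 (0.0520), the stress-response call without wild-type HFD replicate 1 (0.0512) and the fibrosis call in 8 of the 12 fits without 1 library, up to 0.303 without wild-type HFD replicate 1, and with the title code as a term (0.0600) or library size in place of TMM (0.129). Periportal genes fell (-0.38, adjusted p = 0.000256, and adjusted p = 0.369 with an estimated correlation), while pericentral (0.37, adjusted p = 0.00114) and adipose genes (2.20, adjusted p = 0.000401) rose, both at adjusted p = 0.276 with an estimated correlation. With the 8-locus level as a term those last 3 lists were not called (adjusted p = 0.669, 0.343 and 0.447).

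Among genes of cell death, Tnfaip3, an inhibitor of NF-kappaB (0.74 ± 0.18), and the BH3-only gene Bcl2l11 (0.57 ± 0.16) rose with HFD. Gsdmd, the pore former of pyroptosis, fell (-0.37 ± 0.11). Of 31 members 3 rose and 1 fell, and the list was not called (0.14, adjusted p = 0.165). In xenobiotic metabolism 4 of 25 genes rose, such as Cyp2c38 (2.24 ± 0.41), and 7 fell, such as Cyp2c55 (-1.82 ± 0.40) and Gsta2 (-1.54 ± 0.31). The list had a median of 0.22, a mean of 0.14 and a test that pointed down (adjusted p = 0.216). Called members of other lists were cyclin D1, Ccnd1 (1.15 ± 0.20), the interleukin-1 antagonist Il1rn (0.88 ± 0.23), Itih3 (-0.96 ± 0.18), Adipoq (2.74 ± 0.74), Usp18 (1.43 ± 0.22), Lipe (1.19 ± 0.16), Dnajb9 (-0.75 ± 0.14) and the urea cycle gene Cps1 (-0.81 ± 0.21). With the 8-locus level as a term Adipoq was at 0.57 and Cps1 at -0.25, and neither was called (adjusted p = 0.862 and 0.628).

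The genotype effect averaged over diets sets 6 Mlkl-/- libraries against 6 wild-type libraries. Beside Mlkl, Osbpl3 fell by 1.26 on the log2 scale (SE 0.18, adjusted p = 0.0260), from 5.69 ± 1.03 to 2.69 ± 0.956 CPM on ND and from 44.1 ± 12.5 to 16.2 ± 2.74 CPM on HFD (SD, n = 3), and Mybph by 1.04 (SE 0.13, adjusted p = 0.0122). These 3 genes were called, with 1927 at an unadjusted p under 0.05. The Osbpl3 call ended without wild-type ND replicates 1 or 2, Mlkl-/- ND replicate 3, wild-type HFD replicate 2 or Mlkl-/- HFD replicate 1 (adjusted p of 0.0557 to 0.126), and the Mybph call without wild-type ND replicate 2 or Mlkl-/- ND replicate 3 (0.0658 and 0.0557). The count rose to 33, 20, 15 and 6 without wild-type HFD replicate 3, Mlkl-/- HFD replicate 3, Mlkl-/- ND replicate 2 and Mlkl-/- HFD replicate 2, and was 2 without wild-type ND replicate 1 or wild-type HFD replicate 2. It was 1 without wild-type ND replicate 2 or Mlkl-/- ND replicate 3. The count was 13 with the title code as a term and 129 with the code level fitted within each genotype, 92 of them lower. That fit called 377 genes (281 lower) at the lower code level and 4 (0 lower) at the higher. Scd1 (-1.03 ± 0.20) and Aqp1 (-0.67 ± 0.13) missed the threshold, both at adjusted p = 0.0866.

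Over both diets, sinusoidal endothelial genes fell as a list with a median of -0.55, and 13 of 14 were lower adjusted over the list alone (adjusted p = 2.99e-20, and adjusted p = 0.154 with an estimated correlation). Fatty acid synthesis fell with a median of -0.46, 6 of 19 genes being lower adjusted over the list alone (adjusted p = 9.68e-11, and adjusted p = 0.154 with an estimated correlation). Lipid droplet and fatty acid oxidation medians were -0.25 and -0.18, with 6 of 24 and 5 of 27 lower adjusted over the list alone. Both had adjusted p = 1.01e-08, and 0.154 and 0.158 with an estimated correlation. Fibrosis, Kupffer cell and macrophage genes fell with medians of -0.45, -0.37 and -0.40 (adjusted p = 2.83e-08, 8.64e-07 and 5.13e-05). With an estimated correlation these were 0.301, 0.326 and 0.367. At the lower and higher code levels the endothelial median was -0.96 and -0.14 and the fibrosis one -0.79 and -0.18. Kupffer medians were -1.04 and 0.16 and macrophage ones -0.95 and 0.004, with no fall at the higher level. Acute phase genes rose with a median of 0.77 and 11 of 17 higher adjusted over the list alone (adjusted p = 2.95e-13, and adjusted p = 0.154 with an estimated correlation), Hp among them at 0.63 (adjusted p = 0.231 over all genes). Male-biased and secreted hepatocyte genes rose with medians of 0.73 and 0.19, 1 of 18 and 6 of 20 higher adjusted over the list alone. Their adjusted p was 3.29e-08 and 3.61e-05, and 0.295 and 0.154 with an estimated correlation. Of these lists 0 members were called over all genes. Further list calls were adipose (-1.67, adjusted p = 0.00251), female-biased (-0.49, adjusted p = 0.00339) and xenobiotic genes (-0.36, adjusted p = 0.00730) downward, at adjusted p = 0.326, 0.326 and 0.367 with an estimated correlation. The stress response (0.36, adjusted p = 0.00150), ribosomal proteins (0.18, adjusted p = 8.64e-07) and cholesterol synthesis (0.15, adjusted p = 0.000583) were called upward, at adjusted p = 0.295, 0.373 and 0.440 with an estimated correlation. Periportal genes (0.14, adjusted p = 0.0234) rose and cell cycle genes (-0.23, adjusted p = 0.0475) fell as lists, at adjusted p = 0.514 and 0.367 with an estimated correlation. The cholesterol call ended with the 8-locus level as a term (adjusted p = 0.680) and without wild-type HFD replicate 1 (0.0520), and the adipose call without wild-type HFD replicate 3 (0.117). Xenobiotic and female-biased calls ended without wild-type ND replicate 3 (0.0814 and 0.0531) or Mlkl-/- ND replicate 3 (0.137 and 0.0533), the xenobiotic one also without Mlkl-/- HFD replicate 3 (0.0851). Periportal and cell cycle calls ended in 6 and 7 of the 12 fits, up to 0.245 without Mlkl-/- HFD replicate 2 and 0.212 without Mlkl-/- ND replicate 3. The cell cycle call also ended with the title code as a term (0.0543) or within each genotype (0.0813) and with library size in place of TMM (0.165).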

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

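Tests chosen only after the result was seen were those of the 8-locus level, title code, single libraries and other cell markers. Those of depth, size of the diet response, histone genes and other splits were planned.

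Camera called 12 lists for the interaction and fry none of them (adjusted p from 0.121 to 0.445). Given here is the median of Mlkl-/- minus wild-type responses. In monocyte-derived and lipid-associated macrophages it was -1.10 (adjusted p = 4.42e-11), in fibrosis and stellate cells -1.05 (1.52e-09), in Kupffer cells -0.91 (3.95e-09) and in sinusoidal endothelium -0.86 (7.86e-11). Cholangiocyte genes had -1.31 (0.000347), cholesterol synthesis -0.71 (3.97e-11) and interferon-stimulated genes -0.39 (1.20e-07), and secreted hepatocyte proteins had 0.44 (0.000196). Each of these 8 lists had adjusted p = 0.280 with an estimated correlation. Lymphocyte genes had 1.05 (0.00770), periportal genes 0.63 (0.000520), male-biased genes 0.41 (0.00374) and ribosomal proteins 0.31 (1.13e-05), at adjusted p = 0.560, 0.503, 0.563 and 0.562 with an estimated correlation. The lymphocyte call ended without wild-type ND replicate 1, Mlkl-/- ND replicate 1, wild-type HFD replicate 3 or Mlkl-/- HFD replicate 2 (adjusted p = 0.144, 0.109, 0.119 and 0.160). The male-biased call ended without wild-type HFD replicates 1 or 2 or Mlkl-/- HFD replicate 2 (0.0652, 0.0527 and 0.103) and the periportal call without Mlkl-/- ND replicate 1 (0.0581).

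The same contrasts were fitted to other splits of the libraries into groups of the same sizes. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split called 766 genes for diet in wild-type (1 of 10 splits called as many, highest other 0) and 5 for genotype on HFD (1 of 10, highest other 1). For diet in Mlkl-/- the real count was 65 and 2 of 10 splits called as many. The highest other split called 642 genes and set Mlkl-/- ND replicate 1 and Mlkl-/- HFD replicates 1 and 2 against the rest, which is the division by title code. A split with that many calls points to a structure of the samples, and with the code level fitted within each genotype the diet count was 68. For genotype on ND the real count was 1 and 3 of 10 splits called as many. Its highest other split, also the division by title code, called 25 genes, and the count was 2 with the code as a term. For the diet average 2 of 100 splits, the real one included, called as many genes as the real 1302, a share under 0.05. The other was 1341, in the split that parted the Mlkl-/- libraries by title code, and with the code as a term the real contrast called 1500. For the genotype average 4 of 100 splits reached the real count of 3, with a highest other of 18. Mlkl, the targeted gene, is among the 3, so part of the count was fixed by the design. The splits thus do not exclude chance for Osbpl3 and Mybph. For the interaction 0 genes were called, a count that all 100 splits reach by construction (highest other 18), so the splits say nothing about chance there.

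HFD called fewer genes in Mlkl-/- livers (65) than in wild-type livers (766). Depth is argued against, since with all libraries thinned to 19435391 counts the wild-type count was at least 12.7 times that of Mlkl-/-. So is the code level, at 68 against 1086 when fitted within genotypes, but single codes are nested in diet and go untested. Without Mlkl-/- ND replicate 1 the counts were 729 against 1233, a ratio of 0.591, so its spread may account for much of the difference. That stays open, as without wild-type ND replicate 3 or wild-type HFD replicate 2 the ratio was 0.664 and 0.683, by a lower wild-type count. The 8-locus level stays open: as a term it left 27 against 158, and within 1 level an arm is a single library. A smaller diet response without Mlkl stays open too, at a median signed difference of -0.23 over 1302 genes (exact permutation test of genotype within diets, one-sided p = 0.095, 38 of 400 relabelings), and at -0.18 without Mlkl-/- ND replicate 1.

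On HFD, 75 markers of sinusoidal endothelium, stellate cells and macrophages were lower in Mlkl-/- livers by a median of -0.90. A lower share of RNA from all cells other than hepatocytes stays open: 36 markers of cholangiocytes, lymphocytes, neutrophils and red blood cells stood higher against the 75 by 1.00 (pooled SD 0.30) in log2 CPM, but by 0.63 (pooled SD 0.32) without the lymphocyte genes, under 2 pooled SD, and cholangiocyte genes fell (median -0.67, adjusted p = 0.00706, and adjusted p = 0.338 with an estimated correlation). The 8-locus level stays open as a contributor: at its higher level the median was -0.81 (pooled SD 0.417), with the same sign. Title code and, at its lower level, the 8-locus level cannot be told apart from genotype for part of the size. Medians were -1.43 at the lower and -0.49 at the higher code level with 1 code effect per genotype over both diets. They were -1.38 and -0.46 from HFD libraries alone, with 1 arm a single animal. A change in these cells or their transcripts with loss of Mlkl on HFD stays open too, as a hypothesis found and tested on the same 6 livers.

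At the 8 loci 6 libraries held 3484 to 9239 summed CPM and 6 held 378 to 656, a gap of 5.31-fold. Diet alone is argued against, because 2 libraries lie on the other side from their diet, genotype alone, because 4 do from theirs (Fisher's exact test, two-sided p = 0.0801 and 0.567), and code level alone, because 3 libraries of each are at the higher level. Carry-over of RNA without a poly(A) tail was tested on 33 histone genes, whose median shift with the level was 0.29 against 3.82 at the 8 loci. Those histone genes averaged only 3.56 CPM, so carry-over of more abundant RNA need not show in them. Rn7sk, a small nuclear RNA without such a tail, moved by 3.26 (edgeR adjusted p = 0.0224), and carry-over stays open. A joint part of genotype with diet or code level stays open. All 3 wild-type ND and all 3 wild-type lower-code libraries are at the lower level, and all 3 Mlkl-/- HFD and all 3 Mlkl-/- lower-code libraries at the higher one. Part of any diet value may come from the level. With the level as a term the diet counts were 158 in wild-type, 27 in Mlkl-/- and 122 on average.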

How the results depend on the processing

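Alternatives chosen after seeing the data were the 8-locus level as a term, the title code fitted within each genotype, and gene lists without single libraries. No paired analysis was possible because the titles give no shared replicate numbers. Over the alternatives, 197 counts and similarity values stayed within 1.5 times or within their spread and 103 moved. Of list calls 1480 kept direction and call, 318 lost the call and 2 reversed, and of values of named genes 2656 stayed on their side of the threshold in the same direction, 596 lost a call, 24 gained one and 0 reversed. RLE size factors moved no count by over 1.5 times. With 3 libraries per group and 19435391 to 32120426 counts each, the spread between animals limits the calls more than depth, and the simulated recovery of 2-fold changes was 11.9% for the interaction. Causes of the shifts below were not tested, save that fewer samples or genes enter some fits by construction.

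Library size in place of TMM called 1102 genes for diet in wild-type, 100 for diet in Mlkl-/-, 36 for genotype on HFD, 1980 for the diet average and 6 for the genotype average. With it the share of higher calls was 83.6% for diet in wild-type against 47.8%, 81.0% against 58.5% for diet in Mlkl-/-, 5.56% against 20% for genotype on HFD and 82.3% against 49.6% for the diet average. The all-gene medians were then shifted by 0.19, 0.07, -0.16 and 0.13 in these comparisons, by -0.06 for genotype on ND and by -0.10 for the interaction and the genotype average. Without the filter (30718 genes) counts were 171 for diet in Mlkl-/-, 10 and 124 for genotype on ND and HFD, 1 for the interaction and 74 for the genotype average. The stricter filter (11521 genes) called 2 genes for genotype on HFD, dispersions without robust estimation 3, and limma-voom called 0 on ND. DESeq2 called 1441 and 498 genes for diet in wild-type and Mlkl-/-, 45 and 382 for genotype on ND and HFD, 48 for the interaction and 201 for the genotype average. Fits of the compared groups only called 1431, 8, 0 and 2 genes in the 4 simple contrasts, in the order diet in wild-type, diet in Mlkl-/-, genotype on ND and genotype on HFD.

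The title code as a term gave 2, 3 and 13 genes for genotype on ND, on HFD and on average. Fitted within genotypes it gave 3, 143 and 129 there and 2 for the interaction. The 8-locus level as a term gave 158, 27, 3 and 8 in the 4 simple contrasts, 2 for the interaction and 122 for the diet average. Without 1 library the counts ran from 63 to 1233 for diet in wild-type, 13 to 729 for diet in Mlkl-/-, 0 to 6 for genotype on ND, 0 to 189 for genotype on HFD, 0 to 4 for the interaction, 616 to 2029 for the diet average and 1 to 33 for the genotype average.

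Lists called were 15 and 12 for diet in wild-type and Mlkl-/-, 13 and 16 for genotype on ND and HFD, 12 for the interaction, 14 for the diet average and 18 for the genotype average. With an estimated correlation 0 were called in each of the 7. The fry test called 10, 2, 0, 3, 0, 9 and 4 in the same order, and the code within genotypes left 8 for genotype on ND. Without 1 library the lists called were 14 to 18, 11 to 15, 10 to 15, 15 to 20, 11 to 15, 13 to 16 and 15 to 18. The adipose list reversed for diet in wild-type with the 8-locus level as a term (adjusted p = 0.905), and the lymphocyte list for diet in Mlkl-/- without Mlkl-/- HFD replicate 2 (adjusted p = 0.985, against 0.00225 without Mlkl-/- HFD replicate 1 as the lowest). The correlation of both diet responses, 0.285, was 0.352 with the 8-locus level, 0.350 with the code within genotypes and 0.758 over called genes, and 0.203 to 0.362 without 1 library.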

Other observations

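The tests of the title code level within each genotype and the single genes given per library were all chosen after the data were seen. Adgre1, which encodes the macrophage marker F4/80, was at 4.07 ± 0.132 CPM in the 3 Mlkl-/- libraries of the lower code level and at 14.5 ± 1.78 CPM in the 3 of the higher level (SD, n = 3; log2 difference 1.77 ± 0.20, adjusted p = 0.00554). Hgf, a growth factor of stellate and endothelial cells, rose from 4.65 ± 0.669 to 12.7 ± 2.84 CPM (1.38, adjusted p = 0.0162) and the coagulation factor gene F8, made in sinusoidal endothelium, by 1.64 (adjusted p = 0.00554). Genes lower at the higher level were the transcription factor Cebpb (-1.24, adjusted p = 0.0223), the xenobiotic oxidase Cyp1a2 (-1.03, adjusted p = 0.0452) and the clock gene Per2 (-1.04, adjusted p = 0.0490). In all 270 genes were called in Mlkl-/- mice, 178 higher and 92 lower, and 0 in wild-type mice by edgeR (1090 at an unadjusted p under 0.05), and 40 genes were called for the difference of the 2 code effects. Kupffer cell genes were higher in Mlkl-/- mice at the higher level by a median of 0.70, with 6 of 15 called (adjusted p = 1.05e-15, and adjusted p = 0.280 with an estimated correlation). All 3 Mlkl-/- libraries of the lower code level and 1 of the 3 of the higher one are at the higher 8-locus level, with which Kupffer genes also differed, by a median of -0.59 (adjusted p = 5.16e-08, and adjusted p = 0.319 with an estimated correlation), so code and 8-locus level are not separated in this genotype. In wild-type mice, lists called lower at the higher code level included Kupffer cells, sinusoidal endothelium and fibrosis genes, with medians of -0.42, -0.50 and -0.44. Their adjusted p was 6.54e-09, 3.84e-19 and 6.92e-08, and 0.322, 0.0564 and 0.491 with an estimated correlation. The Kupffer list by code and genotype had a median of 1.16 (adjusted p = 3.53e-24, and 0.0517 with an estimated correlation).

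Some genes varied widely between libraries of 1 group. Saa1, an acute phase gene, was at 28.6, 33.0 and 365 CPM in wild-type ND replicates 1 to 3 and at 790, 507 and 1772 CPM in Mlkl-/- ND replicates 1 to 3. On HFD it was at 103, 96.1 and 40.5 CPM in wild-type and at 269, 123 and 1304 CPM in Mlkl-/- replicates 1 to 3. Every Mlkl-/- library was thus above every wild-type library of its diet, and the gene was not called for genotype on ND (2.84, adjusted p = 0.904) or on HFD (2.82, adjusted p = 0.330). The immunoglobulin gene Ighm was at 151 CPM in wild-type ND replicate 1, 125 and 81.3 CPM in Mlkl-/- HFD replicates 2 and 3, and 5.45 to 24.5 CPM in the other 9 libraries. Hsd3b5, a male-biased steroid gene, was at 0.681, 0.0607 and 58.9 CPM in wild-type HFD replicates 1 to 3, while Cyp2b9, a female-biased cytochrome P450, was at 55.2, 107 and 1.59 CPM in the same libraries.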
